A study of Homo sapiens with 9 samples.

How the data were processed

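Polyadenylated RNA of HEK293 Freestyle cells was prepared as TruSeq libraries and sequenced from single ends on a HiSeq 2000. The cells had been held for at least 18 h at 1000000 cells/mL in Freestyle medium, washed, brought to 4000000 cells/mL and plated for 36 h into untreated medium (full), Zn(II)-depleted medium (depleted) or depleted medium with Zn(II) added back (repleted). There were 9 libraries, 3 per group, each a column of its own, and 0 columns of unknown sample.

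The deposited table gives each gene as log2 of RPKM plus 1 by the authors, on Ensembl gene identifiers. The processing notes list the builds hg19 and GRCh37, RSEM 1.2.6, Bowtie 1.0.1, BWA 0.7.12-r1039 and bedtools 2.25.0.3, with no role or order stated. Whether the values were scaled further between libraries is not stated. Checked on the values, 100% were multiples of 0.01 RPKM after the log was undone (tolerance 2e-04 RPKM), the lowest was 0, and RPKM summed over genes weighted by effective length came to between 1 and 1.007 of the total that the unit implies. The effective length was the length less a median of 49 nucleotides. It held 57766 genes and 20320 blank rows.

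Read counts were not used here, since the table holds none. The depth was estimated from the smallest steps between low values of genes with an effective length of 100 to 500 nucleotides, taken as 1 read. Between 64.6% and 67.3% of the checked low values of a library were whole numbers of reads within 0.1 read. These estimates, between 17000000 and 23400000 reads, are not stated totals, and no interval or floor was computed from them. A gene at 0 in a group is described as listed at 0, with no fold change.

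Since the planned count model needs counts, limma 3.58.1 in R 4.3.3 was used on the deposited log2 values, with a trend of the variance on the mean, in a single model with 1 mean per group over all 9 libraries. Genes with at least 1 RPKM in at least 3 libraries were tested, 15774 in all, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. The pseudocount was 1. The 3 comparisons were depleted against full, depleted against repleted and repleted against full medium. The residual correlation of libraries with the same replicate number was between -0.014 and 0.073, and of those with other numbers between -0.061 and 0.042. The highest value came from a pair with the same number, and the second principal component rose with the replicate number in every group. An effect shared by replicate number is therefore not excluded. The main model held no block, and the replicate number as a block served as an alternative.

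Gene lists, 31 in all, were written before the data were examined and tested with camera in limma at a preset correlation of 0.01, adjusted over the 93 tests of 31 lists and 3 comparisons. Lists with at least 3 tested members were used. The same test with an estimated correlation and fry, a rotation test that does not compare a list with other genes, served as alternatives. A further 7 lists were written after the table of all genes, which holds the values of their tested members, had been seen. They were tested as a separate family of 21 tests, which are not independent of these data.

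The genes named were set by a rule written before the data were examined. It takes the 10 largest rises and 10 largest falls of each depleted comparison among called genes with a mean of at least 1 RPKM and no overlap between the groups' libraries, and the 5 largest each way of repleted against full medium. It adds every tested metallothionein, SLC30 and SLC39 gene and up to 4 members of each other list with the smallest p in depleted against full medium. The rule was written for CPM, and RPKM stood in for them. XIST and Y-linked genes were not named. Genes named outside the rule are NQO1, the pseudogene RP3-365I19.2, REST and members of the 7 added lists, together with SCG3, AP3B2 and SYT11, which were chosen after their values were seen.

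Measures of library composition were compared with exact two-sided permutation tests, adjusted over 27 comparisons. The correlation and covariance of the depleted comparisons were set against 100 simulations of unchanged groups that share libraries. The model was tested on simulated data with 50 genes shifted by each of 4 sizes over 15774 genes, and camera on 30 simulated lists of 25 genes, of which it called both lists shifted by 0.5 on the log2 scale and 0 of the unshifted ones. Alternatives were a pseudocount of 0.1, no filter, only the 6 libraries of the groups compared, the replicate number as a block, each library left out in turn and a threshold of 0.01. A mean of at least 1 RPKM as the filter, median centring, quantile normalization and protein-coding genes alone were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Coordinates were left out because the annotation at hand follows a later build than the deposited values, and raw reads were not used.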

Results

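Polyadenylated RNA was sequenced from HEK293 Freestyle cells, an established human embryonic kidney line adapted to growth in suspension, after 36 h in 3 media. The media were untreated Freestyle medium (full), the same medium depleted of Zn(II) (depleted), and depleted medium with Zn(II) added back (repleted). Each group held 3 libraries, which the labels describe as biological triplicates, 9 in all. Expression was given per gene as log2 of RPKM, reads scaled by gene length and library total, plus 1. No read counts were used. The spacing of low values of short genes gave an estimated depth of 23400000, 21300000 and 19200000 reads in the full, 21600000, 21800000 and 18800000 in the depleted and 19200000, 17000000 and 18900000 in the repleted libraries. All RPKM values below are means ± SD with n = 3 per group, and all log2 changes are on the log2(RPKM + 1) scale, which understates the changes of weakly expressed genes. No chromosome positions are given, because the values rest on build hg19 and the annotation at hand on a later build.

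The depleted libraries stood apart from the other 6. Across the 15774 genes tested, which are not independent replicates, Pearson's r between libraries of 1 group lay between 0.983 and 0.9874. It lay between 0.9819 and 0.9858 for full against repleted libraries and between 0.9356 and 0.941 for depleted libraries against the rest. The first principal component held 65.7% of the variance and placed the depleted libraries between 52.53 and 53.55 and the others between -27.5 and -25.77. The second held 6.49% and placed repleted replicates 1 and 2 at -19.13 and -19.03 but repleted replicate 3 at 6.7, beside the full libraries (6.8 to 15.44). Depleted replicates 1, 2 and 3 lay at -8.14, 1.55 and 6.82 on it, and replicate 3 was the highest of each group. For shares of a library, RPKM was summed over genes weighted by effective length. Mitochondrially encoded genes took 1.863% ± 0.0666 of this length-weighted sum in depleted, 1.42% ± 0.105 in full and 1.457% ± 0.0666 in repleted libraries. Ribosomal protein genes took 6.923% ± 0.181, 6.487% ± 0.0907 and 6.55% ± 0.0781. In 27 comparisons of library measures, the smallest exact two-sided permutation p that 3 against 3 libraries allow is 0.1, and no adjusted p was below 0.245.

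Depleted against full medium addresses the response to zinc starvation. The metallothioneins, small cysteine-rich proteins that bind zinc, had the largest falls among the named protein-coding genes. MT2A (ENSG00000125148) fell from 191 ± 8.9 RPKM in full to 6.46 ± 0.687 in depleted medium, 29.6-fold lower (log2 -4.69, SE 0.07, limma adjusted p = 8.5e-10). MT1X (ENSG00000187193) fell from 151 ± 12.2 to 1.78 ± 0.663 RPKM, 84.8-fold lower, and MT1F (ENSG00000198417) from 46.8 ± 1.85 to 1.44 ± 0.361, 32.5-fold lower. These were the 3 tested metallothioneins of 13 listed. Every member tested fell, over all genes tested and adjusted over the list alone, and the list fell as a set (median log2 -4.69, camera adjusted p = 0.00281, but adjusted p = 0.0905 with an estimated correlation). Metallothionein transcripts are similar in sequence, so reads may be shared among them.

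The zinc transporter families moved in mixed directions. SLC30A1 (ENSG00000170385), the exporter of the plasma membrane, fell from 16.4 ± 0.369 to 6.93 ± 0.276 RPKM (log2 -1.14, SE 0.06, limma adjusted p = 3.1e-07). SLC30A2 fell from 1.66 ± 0.291 to 0.09 ± 0.07 RPKM, while SLC30A7 rose by 0.49 on the log2 scale (limma adjusted p = 0.00307). The importer SLC39A10 (ENSG00000196950) rose 2.9-fold, from 17.2 ± 0.645 to 49.9 ± 1.22 RPKM (log2 1.48, SE 0.05, limma adjusted p = 1.55e-08). SLC39A7, which releases zinc from the endoplasmic reticulum, rose from 52.8 ± 1.78 to 85.1 ± 1.84 RPKM. Smaller rises in SLC39A1, SLC39A3, SLC39A6, SLC39A9 and SLC39A13 had log2 values of 0.34, 0.39, 0.22, 0.36 and 0.31. SLC39A4 fell from 32.1 ± 1.94 to 11.4 ± 0.96 RPKM (log2 -1.42, SE 0.07), and SLC39A11 by 0.59 on the log2 scale. SLC39A8 (log2 0.09), SLC39A14 (0.12), SLC30A4 (0.02) and SLC30A9 (-0.07) did not pass the test, although SLC30A9 passed after quantile normalization (limma adjusted p = 0.0464). Of the 11 tested importers 7 rose and 2 fell (camera adjusted p = 0.0823), and of the 9 tested exporters 2 rose and 5 fell (camera adjusted p = 0.398), with the same counts adjusted over the list alone, and neither list passed. The calls of SLC30A3 (log2 -0.48), SLC30A5 (-0.2), SLC30A6 (0.21) and SLC30A10 (-0.4) were not stable: their limma adjusted p of 0.018, 0.033, 0.0431 and 0.0462 ranged up to 0.0683, 0.118, 0.15 and 0.147 over 17 alternatives. SLC30A3 was lost without full replicate 1 (0.0683), depleted replicate 1 (0.0623) or depleted replicate 2 (0.0562), and SLC30A5 without full replicate 3 (0.118), depleted replicate 2 (0.0649) or depleted replicate 3 (0.115). SLC30A6 and SLC30A10 were each lost without any 1 of 7 libraries, all but full replicate 1 and depleted replicate 2.

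**Figure D1:**
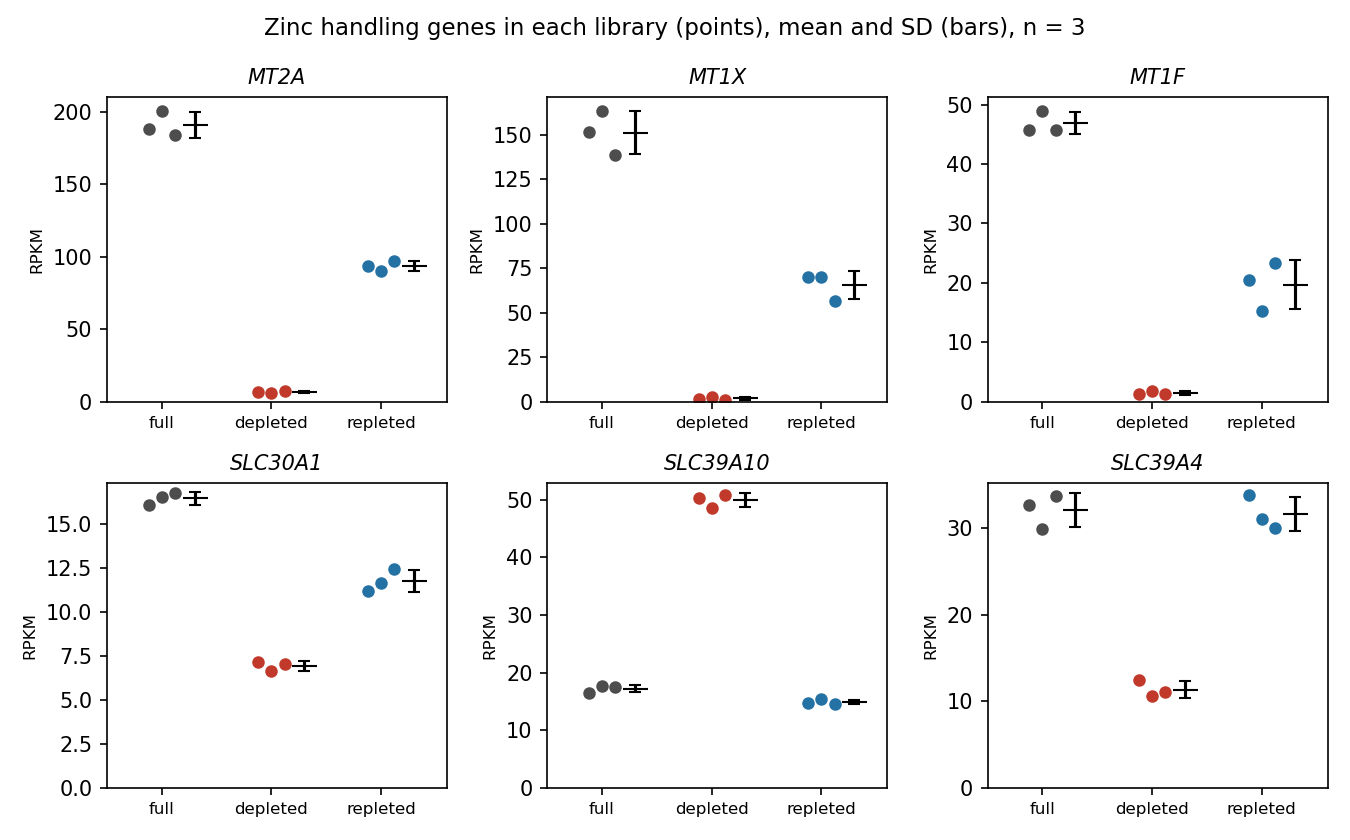
RPKM of 6 zinc-handling genes in each library (points) with the mean and SD of the 3 libraries of each medium, 1 panel per gene. MT2A, MT1X, MT1F, SLC30A1 and SLC39A4 were lower in depleted than in full medium, and SLC39A10 rose from 17.2 to 49.9 RPKM.

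Beyond zinc handling, the largest rises of known protein-coding genes were in CIB3, DHRS2, PRRG2 and CHAC1. DHRS2 (ENSG00000100867), a short-chain dehydrogenase, rose 20.5-fold, from 5.23 ± 0.603 to 107 ± 6.01 RPKM (log2 4.11, SE 0.08, limma adjusted p = 1.53e-09). CHAC1 (ENSG00000128965), an enzyme that degrades glutathione, rose 12.7-fold from 2.38 ± 0.176 RPKM. CIB3 rose from 0.0833 ± 0.144 to 19.7 ± 0.393 RPKM and PRRG2 from 0.49 ± 0.142 to 20.3 ± 2.33. The other largest rises were in the noncoding RP11-3P17.5, RP11-805L22.3, RP11-20D14.6 and RP11-70C1.1 and in the short mitochondrial tRNAs MT-TI and MT-TK, with log2 values from 2.85 to 4.5. The full libraries varied widely for RP11-3P17.5 (7.39 ± 12.8 RPKM). Among protein-coding genes, the largest fall after the metallothioneins was in COQ3 (ENSG00000132423), a methyltransferase of coenzyme Q synthesis, 17.2-fold from 25.6 ± 2.72 RPKM (log2 -3.42, SE 0.1, limma adjusted p = 1.23e-08). CDKN2AIPNL fell from 64.2 ± 3.71 to 5.3 ± 0.186 RPKM and EEFSEC, the elongation factor for selenocysteine, from 27.4 ± 1.05 to 1.79 ± 0.135. The mitochondrial lipid kinase AGK fell from 45.9 ± 1.36 to 4.17 ± 0.47 RPKM, and TTC5 and RASL10B fell 14.7-fold and 12.6-fold. The antisense transcript RP11-138I1.4, also among the largest falls, had 50.8 ± 18.5 RPKM in full medium and was listed at 0 in all 3 depleted libraries, so no fold or rank is given for it.

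Stress and lysosomal genes rose together. Of 28 tested targets of ATF4, the transcription factor of the integrated stress response, 26 rose and 1 fell (median log2 1.04, camera adjusted p = 1.52e-11, but adjusted p = 0.0754 with an estimated correlation). Among them the asparagine synthetase ASNS rose from 50.2 ± 2.13 to 151 ± 5.2 RPKM, CTH from 7.32 ± 0.273 to 33 ± 2.2 and SESN2 from 16.3 ± 0.541 to 45 ± 1.98. Of 27 lysosome and autophagy genes 22 rose and 1 fell (median log2 0.38, camera adjusted p = 1.4e-06, adjusted p = 0.0594 with an estimated correlation). The protease CTSD rose from 83.1 ± 0.666 to 168 ± 0.728 RPKM, the lysosomal membrane protein gene LAMP1 from 49.4 ± 0.251 to 87.5 ± 0.352 and the autophagosome protein gene MAP1LC3B from 42.4 ± 1.47 to 87.6 ± 2.58. Of 25 genes of the unfolded protein response in the endoplasmic reticulum 17 rose and 4 fell (median log2 0.24, camera adjusted p = 0.0244, adjusted p = 0.154 with an estimated correlation and 0.0539 after quantile normalization, the highest of 16 settings, from 0.00239). MANF rose from 69 ± 3.05 to 118 ± 7.51 RPKM and XBP1 from 50.2 ± 1.13 to 70 ± 3.62, while the chaperone HSP90B1 fell from 298 ± 7.14 to 244 ± 5.53. Of 22 p53 targets 14 rose and 5 fell (median log2 0.4, camera adjusted p = 0.0244, adjusted p = 0.252 with an estimated correlation). BAX, which promotes apoptosis, rose from 204 ± 2.91 to 393 ± 10.2 RPKM and GADD45A from 53.4 ± 1.73 to 107 ± 2.06, while BTG2 fell from 25.8 ± 1.27 to 14.6 ± 0.293. Adjusted over the list alone, the counts of these 4 lists were the same.

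Genes of the extracellular matrix, ribosome biogenesis and glycolysis fell. Of 20 matrix genes 3 rose and 15 fell, 4 and 15 adjusted over the list alone (median log2 -0.57, camera adjusted p = 0.00594, adjusted p = 0.252 with an estimated correlation). SPARC fell from 139 ± 1.26 to 63.4 ± 2.7 RPKM, VCAN from 29 ± 2.11 to 8.07 ± 1.18 and LAMB1 from 16.8 ± 0.236 to 5.3 ± 0.261. Of 24 ribosome biogenesis genes 2 rose and 15 fell, with the same counts adjusted over the list alone (median log2 -0.24, camera adjusted p = 0.00594, adjusted p = 0.0905 with an estimated correlation). PES1 fell from 85 ± 4.39 to 34.3 ± 1.52 RPKM and the nucleolar NPM1 from 2330 ± 57.6 to 1480 ± 33.1. Of 17 glycolysis genes 2 rose and 11 fell, again the same adjusted over the list alone (median log2 -0.25, camera adjusted p = 0.0237, adjusted p = 0.265 with an estimated correlation). Median centring of the libraries ended this call (adjusted p = 0.071, the highest of 16 settings, from 0.00056). The pyruvate kinase PKM fell from 634 ± 6.02 to 385 ± 3.37 RPKM and the enolase ENO1 from 1630 ± 15.8 to 1170 ± 13.2.

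Transcripts for ribosomal proteins and those encoded in mitochondria rose as lists. Both held a higher share of the length-weighted RPKM sum in depleted than in full libraries (6.923% against 6.487%, and 1.863% against 1.42%). Of 83 ribosomal protein genes 46 rose and 14 fell, 49 and 15 adjusted over the list alone (median log2 0.11, camera adjusted p = 0.0028, adjusted p = 0.688 with an estimated correlation). Their call ended after quantile normalization (adjusted p = 0.1, the highest of 16 settings, from 0.000181). RPS26 and RPL21, which have many pseudogenes, rose to 69.7 ± 2.02 and 178 ± 3.24 RPKM from 26.1 ± 0.344 and 58.6 ± 6.42, while RPL10 fell from 1550 ± 5.89 to 908 ± 35.7. Of 15 mitochondrially encoded genes 11 rose and 2 fell, with the same counts adjusted over the list alone (median log2 0.24, camera adjusted p = 0.0407, adjusted p = 0.688 with an estimated correlation). The ribosomal RNA gene MT-RNR2 rose from 507 ± 48 to 1240 ± 76.1 RPKM and MT-CO1 from 1930 ± 161 to 3450 ± 77.7. This list held in 10 of 16 settings (adjusted p from 0.00707 to 0.137) and was lost with replicate number as a block, after quantile normalization, among protein-coding genes and without full replicate 1, full replicate 2 or repleted replicate 1.

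**Figure D2:**
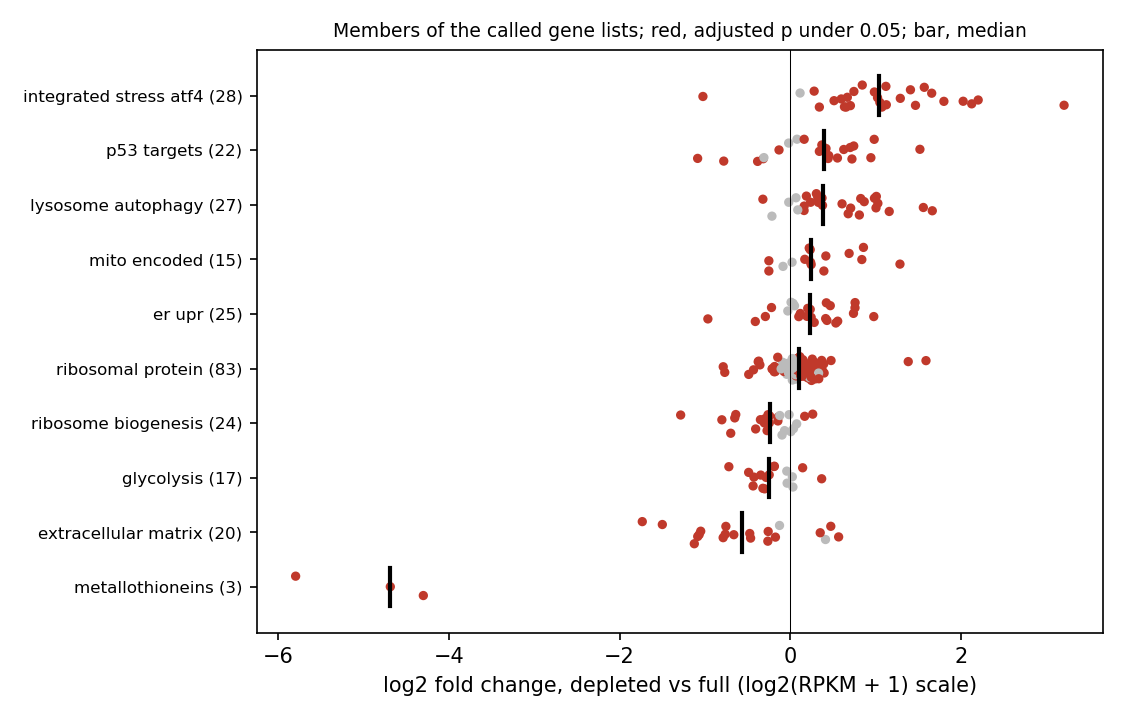
Log2 change in depleted against full medium of each tested member of the 10 lists that passed (points, red where the limma adjusted p is under 0.05), with the list's median as a bar and the number of members tested in brackets. Of the 28 ATF4 targets 26 rose, and all 3 metallothioneins fell; the ribosomal protein, mitochondrially encoded and unfolded protein response lists lost their call after quantile normalization and the glycolysis list after median centring, and all 10 lost it with an estimated correlation (adjusted p from 0.0594 to 0.688).

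The other lists did not pass. In this comparison 60.9% of all genes tested were called, 4693 higher and 4918 lower, so called members alone do not set a list apart. Of 30 zinc-dependent enzymes 8 rose and 17 fell (camera adjusted p = 0.112). The deacetylase HDAC8 fell from 21.8 ± 2.07 to 2.81 ± 0.567 RPKM and LTA4H from 72 ± 0.763 to 37.9 ± 1.36. Of 408 zinc finger genes 122 rose and 98 fell (camera adjusted p = 0.598), and ZNF580 fell from 44.8 ± 4.1 to 12.2 ± 0.506 RPKM. Among genes of other metals, 3 of 15 iron genes rose and 7 fell (adjusted p = 0.61), 3 of 12 copper genes rose and 3 fell (0.972), and 2 of 7 manganese and calcium transport genes rose and 2 fell (0.812). The transferrin receptor TFRC fell from 38 ± 5.69 to 21 ± 1.6 RPKM, and SOD1 rose from 320 ± 6.7 to 394 ± 15.4. Cholesterol synthesis (9 of 24 rose, 9 fell, 0.855), fatty acid synthesis (6 of 16 rose, 5 fell, 0.952) and NRF2 targets (10 of 22 rose, 9 fell, 0.863) were mixed, and SLC7A11 rose from 3.77 ± 0.0874 to 19.9 ± 1.75 RPKM. Of 21 heat shock genes 7 rose and 9 fell (0.632). DNAJB1 rose from 59.9 ± 1.89 to 151 ± 2.98 RPKM, while HSP90AB1 fell from 992 ± 1.54 to 521 ± 6.61. Hypoxia targets (7 of 25 rose, 10 fell, 0.89) included VEGFA, which rose from 12.8 ± 0.526 to 42.6 ± 0.356 RPKM. Cell death genes (10 of 22 rose, 5 fell, 0.535), genes of S phase (13 of 29 rose, 6 fell, 0.234) and of mitosis (7 of 32 rose, 15 fell, 0.521) did not pass. BIRC5 fell from 121 ± 3.66 to 50.9 ± 3.6 RPKM and PLK1 from 82.2 ± 1.3 to 37.2 ± 1.33.

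Immediate early genes (12 of 23 rose, 5 fell, camera adjusted p = 0.0864) and targets of NF-kB (5 of 7 rose, 1 fell, 0.0943) did not pass either, although RELB rose from 1.52 ± 0.131 to 12.5 ± 0.726 RPKM and NFKB2 from 13.9 ± 1.16 to 35.9 ± 0.392. MYC fell from 42.1 ± 2.57 to 23.6 ± 0.244 RPKM. Interferon-stimulated genes (6 of 15 rose, 1 fell, 0.305), DNA repair genes (11 of 22 rose, 6 fell, 0.426) and replication-dependent histones (7 of 27 rose, 4 fell, 0.516) had few or mixed changes. Of 21 markers of other cell lineages, 3 passed the expression filter: LUM fell from 8.96 ± 1.07 to 3.5 ± 0.352 RPKM, HBA1 rose from 1.41 ± 0.587 to 4.15 ± 0.586, and DES had 0.967 ± 0.431 in full and 1.16 ± 0.265 in depleted medium. The median, mean and test differed in sign for cholesterol synthesis, fatty acid synthesis, heat shock, zinc finger genes and lineage markers. Adjusted over the list alone, the counts that rose and fell were 4 and 7 for iron, 8 and 10 for hypoxia, 11 and 7 for cell death, 8 and 15 for mitosis, 5 and 1 for interferon-stimulated genes, 118 and 96 for zinc finger genes and 7 and 2 for histones, and the same as above for the other lists that did not pass.

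In total 9611 of 15774 genes (60.9%) passed the limma test in depleted against full medium, 4693 higher and 4918 lower, of which 519 rose and 1074 fell at least 2-fold. The balance of the calls depended on the scaling, with 5186 higher and 4498 lower after median centring and 5062 higher and 4538 lower after quantile normalization. The 3 depleted and the 3 full libraries did not overlap for 67.6% of genes, against 10% by chance. With changes added to simulated libraries of the same size, 18% of genes shifted by 0.25, 48% of those shifted by 0.5 and 94% of those shifted by 1 on the log2 scale were recovered, with 1 false call. Only 50 of 15774 genes were shifted by each size, which makes the adjusted threshold stricter than where most genes change, so these shares do not carry over to the depleted comparisons.

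Depleted against repleted medium isolates Zn(II) from anything else that the depletion step removed. MT2A was 14.5-fold lower in depleted than in repleted medium (6.46 ± 0.687 against 93.5 ± 3.34 RPKM, log2 -3.67, SE 0.07, limma adjusted p = 1.28e-09). MT1X and MT1F were 36.9-fold and 13.7-fold lower, and SLC30A1 had 6.93 ± 0.276 against 11.7 ± 0.635 RPKM (log2 -0.68). SLC39A10 was 3.35-fold higher in depleted medium (log2 1.68, SE 0.05, limma adjusted p = 7.48e-09). SLC39A7 was higher by 0.65 on the log2 scale, and SLC39A4 had a log2 change of -1.4. DHRS2, CIB3, PRRG2 and CHAC1 were again among the largest rises, with log2 values of 3.97, 4.1, 3.74 and 3.16. They were joined by the acyl-CoA synthetase ACSBG1, which had 9.44 ± 0.756 RPKM in depleted and 0.56 ± 0.2 in repleted medium, and by SNORD82, listed at 0 in all 3 repleted libraries. The antisense transcript ENSG00000223478 and the pseudogene SNRPEP4 rose by 2.99 and 2.94 on the log2 scale, MT-TI by 2.86 and RP11-20D14.6 by 2.82. RP11-138I1.4 was listed at 0 in the depleted libraries and had 52.6 ± 40.8 RPKM in the repleted ones. COQ3, CDKN2AIPNL, AGK, EEFSEC and RASL10B were again among the largest falls. MFSD3 had 3.26 ± 0.289 against 36.3 ± 2.17 RPKM, and TAMM41, a mitochondrial lipid enzyme, 1.13 ± 0.429 against 17.3 ± 0.0529. RP11-3P17.5 had 79.6 ± 20.8 RPKM in repleted and 64.9 ± 15.9 in depleted medium.

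In that comparison 9 of the 31 lists passed. ATF4 targets (26 of 28 rose, 1 fell, camera adjusted p = 1.89e-11, adjusted p = 0.0754 with an estimated correlation) and lysosome genes (22 of 27 rose, 1 fell, 5.08e-07, adjusted p = 0.0594 with an estimated correlation) rose. Genes of the unfolded protein response (17 of 25 rose, 4 fell, 0.0102, adjusted p = 0.104 with an estimated correlation) and p53 targets (14 of 22 rose, 3 fell, 0.0109, adjusted p = 0.226 with an estimated correlation) rose. The metallothioneins (3 of 3 fell, 0.00548, adjusted p = 0.104 with an estimated correlation), ribosome biogenesis (2 of 24 rose, 17 fell, 0.00577, adjusted p = 0.0905 with an estimated correlation) and matrix genes (3 of 20 rose, 15 fell, 0.00831, adjusted p = 0.252 with an estimated correlation) fell. Glycolysis (2 of 17 rose, 11 fell, 0.0284, adjusted p = 0.274 with an estimated correlation) fell, but its adjusted p was 0.0841 after median centring, the highest of 16 settings, from 0.00137. Ribosomal protein genes (45 of 83 rose, 14 fell, 0.00807, adjusted p = 0.688 with an estimated correlation) rose, but their adjusted p was 0.179 after quantile normalization, the highest of 16 settings, from 0.000766. They took 6.923% of the length-weighted RPKM sum in depleted and 6.55% in repleted libraries. Mitochondrially encoded genes did not pass (8 of 15 rose, 2 fell, 0.0829), although they took 1.863% of the length-weighted RPKM sum in depleted and 1.457% in repleted libraries. Adjusted over the list alone, 2 ribosome biogenesis genes rose and 18 fell, 4 matrix genes rose and 16 fell, and 46 ribosomal protein genes rose and 14 fell, with the other counts as given. A total of 9574 genes (60.7%) passed the limma test, 4654 higher and 4920 lower in depleted medium, but 5160 higher and 4398 lower after median centring and 5057 higher and 4445 lower after quantile normalization. The libraries did not overlap for 65.2% of genes, against 10% by chance.

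Most genes that changed in depleted against full medium also changed against repleted medium. A total of 8661 genes passed in both comparisons in the same direction, 4190 higher and 4471 lower in depleted medium, and 1 gene passed in opposite directions. At least 2-fold changes in both were seen for 413 rises and 904 falls. For lists of these sizes drawn independently, 1385 shared rises and 1534 shared falls would be found. Both comparisons use the same 3 depleted libraries, which are too few to divide, so part of this excess may come from the shared libraries. In 100 simulations of unchanged groups that share libraries, a median of 0 genes and at most 1 passed in both. Since no group differed in these simulations, they do not tell how large that part is where most genes change. The log2 changes correlated across genes with Pearson's r of 0.9425, against a median of 0.502 in 100 simulations of unchanged groups that share libraries, and their covariance was 0.3875 against 0.0147. Genes are not independent replicates, and r was 0.9753 among protein-coding genes.

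**Figure D3:**
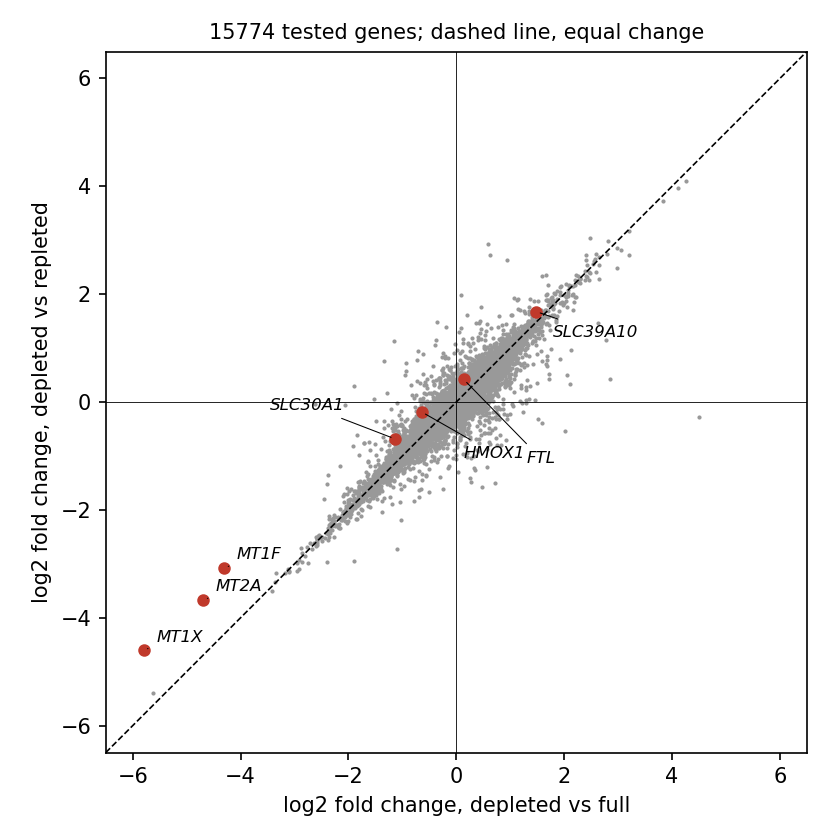
Log2 change of 15774 genes in depleted against full medium (x axis) and in depleted against repleted medium (y axis), with equal change as a dashed line and 7 genes labelled. Most points follow the line, and MT1X, MT2A and MT1F lie above it, at -5.8, -4.69 and -4.3 on the x axis and -4.6, -3.67 and -3.07 on the y axis.

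Repleted against full medium asks what adding Zn(II) back did not restore. MT2A had 93.5 ± 3.34 RPKM in repleted and 191 ± 8.9 in full medium, 2.04-fold lower (log2 -1.02, SE 0.07, limma adjusted p = 0.00114), and MT1F had 19.7 ± 4.07 and 46.8 ± 1.85 RPKM (log2 -1.23, SE 0.15, limma adjusted p = 0.0382). HMOX1 (ENSG00000100292), the heme oxygenase, fell from 53 ± 2.32 in full to 38.4 ± 0.76 RPKM in repleted medium (log2 -0.45, SE 0.05, limma adjusted p = 0.0282). It had 33.7 ± 1.46 RPKM in depleted medium (log2 -0.64 against full). FTL (ENSG00000087086), the light chain of the iron store ferritin, fell from 910 ± 18.1 to 751 ± 29.5 RPKM (log2 -0.28, SE 0.03, limma adjusted p = 0.0282), whereas it was 1003 ± 19.4 in depleted medium. The fifth call was the pseudogene RP3-365I19.2, with 2.04 ± 0.509 RPKM in full medium and listed at 0 in the repleted libraries. It had 0.0467 ± 0.0808 RPKM in depleted medium (limma adjusted p = 4.6e-05 against full). MT1X had 65.6 ± 7.99 against 151 ± 12.2 RPKM and SLC30A1 11.7 ± 0.635 against 16.4 ± 0.369, both at a limma adjusted p of 0.0596, above the threshold. NQO1, chosen after its values were seen, had 12.1 ± 0.408 against 17.9 ± 0.784 RPKM at the same adjusted p. No SLC30 or SLC39 gene was called, and SLC39A10 had 14.9 ± 0.389 against 17.2 ± 0.645 RPKM.

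These 5 genes were all lower in repleted medium, whose replicate 3 stood apart from the other 2 on the second principal component. In this comparison 1224 genes had an unadjusted limma p under 0.05, and the libraries did not overlap for 12.4% of genes against 10% by chance. MT2A was called in all 17 alternatives (adjusted p from 0.000116 to 0.0174), but MT1F in 4 of 17 (0.00883 to 0.227) and HMOX1 and FTL in 8 of 17 each (0.0087 to 0.212). The MT1F call was lost without any 1 of the 9 libraries, the HMOX1 call without any of 6 (all but full replicate 1, depleted replicate 1 and depleted replicate 3) and the FTL call without any of 6 (all but full replicate 1, depleted replicate 1 and repleted replicate 1). MT1X passed in 6 of 17 alternatives (0.016 to 0.292), without depleted replicate 2 or 3 among them, and SLC30A1 in 1 (0.0489 to 0.375). The count of calls was 9 without full replicate 1, 6 without depleted replicate 1 and 2 without full replicate 2 or depleted replicate 2. It was 3 without depleted replicate 3, repleted replicate 1 or repleted replicate 2, and 1 without full replicate 3 or repleted replicate 3. Of these calls, 3 were higher in repleted medium without full replicate 1, 1 without full replicate 2 and 1 without depleted replicate 1, and the rest were lower. Of the genes called in the same direction in both depleted comparisons, 4 were also called here: MT2A, MT1F, HMOX1 and FTL. Over the 1317 genes changed at least 2-fold in both depleted comparisons, the median share of the log2 change against full medium that remained in repleted medium was -0.271% (quartiles -5.5 and 4.84). It exceeded 20% for 26 genes, among them MT1F (28.5%), MT2A (21.8%) and MT1X (20.7%). In RPKM a larger part of their fall remained. Means in full, depleted and repleted medium were 191, 6.46 and 93.5 for MT2A, 151, 1.78 and 65.6 for MT1X and 46.8, 1.44 and 19.7 for MT1F. Requiring a change against repleted medium leaves out genes that kept much of theirs. For the 1588 genes chosen by a 2-fold change against full medium alone, metallothioneins and zinc exporters aside, the median share of the log2 change was 1.65% (quartiles -4.22 and 8.51), and 143 exceeded 20%.

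As sets, the metallothioneins fell (median log2 -1.2, camera adjusted p = 3.96e-11), with 2 of 3 called and 3 adjusted over the list alone, and this call held with an estimated correlation (adjusted p = 0.0345). Lists of NRF2 targets (median -0.09, 1.14e-09, adjusted p = 0.0905 with an estimated correlation), zinc exporters (-0.24, 0.000258, adjusted p = 0.0754 with an estimated correlation) and iron genes (-0.11, 0.00046, adjusted p = 0.0754 with an estimated correlation) fell. Of 22 NRF2 targets 2 fell and of 15 iron genes 1 fell, while none of 9 exporters was called; adjusted over the list alone, 7, 3 and 3 fell and none rose. The NRF2 and iron lists share FTL and FTH1, and FTL is the 1 iron gene called, so they are not separate evidence. Without these 2 genes, NRF2 targets (median -0.07, adjusted p = 6.85e-07, adjusted p = 0.139 with an estimated correlation) and iron genes (-0.09, 0.0325, adjusted p = 0.191 with an estimated correlation) still fell, a test added after seeing the data. Shifts of at most 0.05 also passed for cholesterol synthesis (0.04, 0.0109, adjusted p = 0.104 with an estimated correlation), ATF4 targets (0.04, 0.0102, adjusted p = 0.37 with an estimated correlation), lysosome genes (-0.05, 0.0104, adjusted p = 0.145 with an estimated correlation) and ribosomal protein genes (0.01, 0.0244, adjusted p = 0.757 with an estimated correlation). No member of these 4 lists was called over all genes tested, and 1 and 2 members of the cholesterol and ATF4 lists rose, 2 lysosome genes fell and no ribosomal protein gene changed adjusted over the list alone. The cholesterol call was lost without repleted replicate 3 (adjusted p up to 0.0743 over 16 settings), the ATF4 call without full replicate 3 (up to 0.0731), the lysosome call without full replicate 1 or repleted replicate 2 (up to 0.0873), and the ribosomal protein call in 7 settings (up to 0.57), among them both scalings and those without full replicate 3, repleted replicate 1 or repleted replicate 3. The remaining lists did not pass in this comparison.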

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

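The alternatives of median centring, quantile normalization, a mean of at least 1 RPKM and protein-coding genes only were chosen after seeing the data. The counts for both depleted comparisons and their overlap stayed within 1.5 times under all alternatives run. At an adjusted p under 0.01, 7604 genes were called in depleted against full and 7541 in depleted against repleted medium. Leaving out 1 library gave 8780 to 9723 and 8784 to 9512 genes, 7905 to 8374 in both and r of 0.9246 to 0.9441. It gave 1 to 9 genes in repleted against full medium, 1 to 4 genes called in all comparisons, and 9 to 10, 9 to 10 and 7 to 10 lists. Of 5384 values of 154 named genes over 17 alternatives, 5285 kept direction and side of the threshold, 66 were weaker, 15 stronger and 18 reversed, 0 of these for a called gene. Median centring moved the median log2 change by 0.046 and 0.05 in the depleted comparisons.

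Where values moved, the cause was not tested, save for the fewer libraries or genes of a setting. In repleted against full medium 2 genes were called with no filter, 3 with pseudocount 0.1, 2 with only the 6 libraries compared, 2 with the replicate block and 1 at an adjusted p under 0.01. Genes called in all comparisons numbered 1 with no filter, 2 with only 6 libraries, 2 with the block, 1 at the stricter threshold and 7 among protein-coding genes. The r was 0.9162 with no filter, 0.8884 with pseudocount 0.1 and 0.9753 among protein-coding genes. With an estimated correlation 0, 0 and 1 lists were called, and with fry 24 in each depleted comparison, since it does not compare a list with other genes. The block called 9511, 9472 and 2 genes, of which 9273, 9256 and 1 were among those called without it. It lost SLC30A6 in depleted against full medium (adjusted p 0.0589) and MT1F (0.18), HMOX1 (0.0518) and FTL (0.18) in repleted against full, and gained MT1X (0.0174).

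The log2 values that reversed were those of uncalled genes near 0. Leaving out 1 library gave in repleted against full medium -0.26 to 0.01 for SLC30A4, -0.06 to 0.06 for SLC39A14, -0.08 to 0.04 for SLC39A11, -0.07 to 0.02 for SLC39A4 and -0.12 to 0.03 for SLC39A3. It gave in depleted against full medium -0.02 to 0.3 for DES and -0.12 to 0.15 for SLC30A4, and in depleted against repleted medium -0.03 to 0.1 for SLC30A5 and -0.03 to 0 for SLC30A9. In the latter comparison SLC30A5 was at 0 after quantile normalization and SLC30A9 at 0.03 after median centring. RLE size factors, library size alone, DESeq2 and limma-voom were not run, as they need counts, and the filter on mean CPM was run on mean RPKM. Depth limits what can be said of genes listed at 0.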

Other observations

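The tests of the medium, of the share of change that remained, of FTL in depleted medium and of the neuronal list were chosen only after the results they concern had been seen, and quantile normalization and the 7 added lists after the data had been seen. Transcripts for mitochondrial ribosomal proteins, chosen as a list after the table of all genes had been seen, fell: 43 of 78 were lower and 19 higher in depleted than in full medium, with the same counts adjusted over the list alone (median log2 -0.22, camera adjusted p = 0.00893, but adjusted p = 0.623 with an estimated correlation). MRPL54 fell from 56.1 ± 3.31 to 6.91 ± 1.57 RPKM (SD, n = 3 per group), MRPL40 from 58.3 ± 2.62 to 13.4 ± 0.153 and MRPS26 from 84.2 ± 0.237 to 23.2 ± 2.02. Against repleted medium 42 were lower and 17 higher (camera adjusted p = 0.00526, adjusted p = 0.623 with an estimated correlation). Lists around other single genes with large falls did not pass: in depleted against full medium 4 of 11 coenzyme Q genes rose and 5 fell (camera adjusted p = 0.601), 8 of 39 complex I genes rose and 17 fell (0.318), and 7 of 18 selenoprotein genes rose and 5 fell (0.715). Nor did tRNA synthetases (10 of 20 rose, 5 fell, 0.513) or the proteasome (17 of 37 rose, 10 fell, 0.519), and the median, mean and test differed in sign for these 2 lists and for selenoproteins. Of 22 mitochondrial tRNAs, with a median length of 69 nucleotides, 10 rose and 0 fell against full medium (median log2 0.93). Against repleted medium 10 rose and 2 fell (median log2 0.4). All of them together took 0.0113% ± 0.000608 of the length-weighted RPKM sum in depleted and 0.0052% ± 0.000323 in full libraries. The effective length was the length less a median of 49 nucleotides, so values of such short genes rest on few positions. The source of these reads in polyadenylated RNA was not tested.

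Most tested genes, 60.9%, changed in depleted medium. Quantile normalization gave 9600 calls, 9009 of them shared with the main test and in the same direction, which argues against library scaling or a few abundant genes. Removal of a trend with gene length gave 9672 calls, 9252 of them shared and in the same direction, which argues against length. Adding Zn(II) back to the depleted medium left 5 calls against full medium, which argues against another change of the medium that zinc does not reverse. A change in the number of cells or their growth that follows from zinc depletion stays open and was not tested, and a broad response to zinc is a hypothesis that graded zinc levels would test. The 10 splits of 6 libraries are too few for a share under 0.05: the real splits gave 9757 and 9227 genes in the depleted comparisons and the highest of the others 0 in each, with 10 lists each against 5 and 6.

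MT2A stayed lower in repleted than in full medium, by -1 on the log2 scale after quantile normalization, which argues against library scaling. With metallothioneins and exporters left out, 1314 genes changed at least 2-fold in both depleted comparisons. They kept a median of -0.276% of their log2 change (95% bootstrap interval over genes -0.687 to 0.224). This choice leaves out genes that kept much of their change. The 1588 genes chosen against full medium alone kept 1.65% (1.08 to 2.29). With 1 full library held out of each choice, the medians ranged from 0 to 0.555% over 3 choices of 1688 to 1731 genes, below the latter interval. The intervals resample genes, which are not independent replicates, and hold no variation between libraries. The low medians argue against a remaining zinc shortage that kept these genes in proportion. FTL changed by 0.14 in depleted against full medium, opposite to its fall in repleted medium. This argues against a remaining zinc shortage for FTL only if FTL moves in 1 direction as zinc falls, which was not tested. Against full medium SLC30A1 was at log2 -0.45 in repleted (limma adjusted p = 0.0596) and -1.14 in depleted medium. The exporter list fell in repleted medium (median -0.24, camera adjusted p = 0.000258, adjusted p = 0.0754 with an estimated correlation). In depleted medium, where 2 exporters rose and 5 fell, it did not pass (camera adjusted p = 0.398), so its fall cannot be read as low zinc. The importer SLC39A10 rose in depleted medium (log2 1.45 to 1.53 over 17 alternatives) but was at -0.22 to -0.18 in repleted medium, not called. A lower level of free zinc than in full medium that metallothioneins and SLC30A1 register is a hypothesis, which measuring free zinc in the 3 media would test. Reads shared among paralogs stay open for MT1F and MT1X. Here the 10 splits of 6 libraries are again too few for a share under 0.05: the real split gave 2 genes and the highest other 5, with 2 splits as large, and 9 lists against 4.

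SCG3, AP3B2 and SYT11, which neurons express, rose in depleted medium, SCG3 from 1.51 ± 0.243 to 14.7 ± 0.923 RPKM, AP3B2 from 2.44 ± 0.503 to 20.4 ± 0.967 and SYT11 from 6.03 ± 0.846 to 36.6 ± 0.356. In a list of other neuronal genes known to be repressed by the zinc finger protein REST, of which 24 of 35 passed the expression filter, 17 rose and 1 fell, the same adjusted over the list alone (median log2 0.79, camera adjusted p = 0.000152, holding at adjusted p = 0.0312 with an estimated correlation), SYN1 from 0.453 ± 0.0666 to 6.13 ± 0.256 RPKM and SNAP25 from 0.72 ± 0.168 to 6.2 ± 0.484. Weak genes can pass the filter through their rise, and with no filter 20 of 35 rose and 2 fell (camera adjusted p = 1.43e-06, 0.00927 with an estimated correlation), whereas of the 16 with a mean of at least 1 RPKM in full medium 11 rose and 1 fell (camera adjusted p = 0.00632, but adjusted p = 0.109 with an estimated correlation). The median of the 24 lay at percentile 100 of 10000 random lists of like expression, as did that of the 16 with lists matched on full medium alone, which argues against a general rise of weakly expressed genes. REST itself, named outside the rule, fell from 8.58 ± 0.926 to 5.48 ± 0.425 RPKM (log2 -0.56, limma adjusted p = 0.000792). In this comparison 4918 of 15774 genes were called lower, so the fall of 1 chosen gene says little. Weaker repression by REST is a candidate explanation, found and tested on the same data, and other regulators of these genes stay open and were not tested.

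Of 100 splits of the 9 libraries into groups of 3, 1 gave as many genes called in both depleted comparisons as the real 8661, the real one itself. The highest of the others gave 8654 and was a split that kept the 3 depleted libraries together, as 3 of the 100 did. Without such splits the highest was 2. The count thus shows that the depleted libraries stood apart. Too few splits kept them together to exclude chance for the overlap itself. For the 4 genes called in all 3 comparisons, 1 split of 100, the real one, gave as many, and the highest other gave 1. Only 2 of the splits, the real one included, called enough genes in both depleted comparisons to reach 4, too few to exclude chance.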
